A study of Rattus norvegicus with 70 samples.

How the data were processed

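The libraries hold rat liver DNA enriched for methylated fragments with a methyl-binding protein (MBD sequencing, MethylMiner kit) and read on a SOLiD 4 sequencer. Rats of the outbred strain Crj:CD(SD)IGS passed through a hepatocarcinogenesis scheme of an initiating treatment followed by promotion. There were 70 libraries in 14 groups of 5, from 7 treatment conditions at 2 times, and the labels say that each group came from 5 rat livers. Groups were taken from the titles and sample labels.

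Per the file headers, each of the 2 region tables holds 1 deposited signal value for every library over the same 17174 regions around transcript starts, 1 table for each time. In every deposited column the values were whole multiples of a single step, so the authors had scaled the reads of each library by its own factor. The step equalled 50 M divided by a whole number, which is called the scaling total here, and a region with no read carried a placeholder of 0.01. Dividing by the step gave whole reads within a tolerance of 0.01 for 100% of the values above the placeholder. What the scaling total counts is not given in the sources used here, nor are the aligner and the genome build. The coordinates printed are those of the files.

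The deposited tables also hold the authors' p-value per region for every group against the group given vehicle and phenobarbital, and per the file headers it came from a t-test. A deposited peak list sets DEN 30 mg/kg against phenobarbital at time points it calls 5w and 11w, which are read here as partial hepatectomy and terminal euthanasia. The second region table carries the time 10W in its name and not 11w, so every comparison of the second time between the peaks and the regions rests on this reading. Per the file headers, the list gives read counts in each peak for the set in which it is higher and for the other set, and a read density. It also gives the authors' enrichment factor, a ratio of the 2 counts times a constant. The caller, its threshold and whether libraries were pooled are not given in the sources used here.

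Each region spanned 5625 bp. Where the peak list gave a distance to a transcript start inside a region, the start lay within 50 bp of a point 4500 bp from the upstream edge in 7473 of 8480 cases (88.1%). The tables named 17052 transcripts with 16561 gene symbols, of which 15826 transcripts were matched to the RefSeq gene table, and 21 symbols written as dates were looked up there through their transcripts. Overlaps were common, since 3657 regions overlapped another and 528 shared the coordinates of another. Counts of regions therefore exceed counts of independent places.

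Signal was taken as log2(value + 1), and a region was tested where at least 5 libraries had a value of 10 or more. This left 15809 regions at partial hepatectomy, 16008 at terminal euthanasia and 16385 for the comparison of the times. limma 3.58.1 in R 4.3.3 fitted 1 mean per group with a trend in the variance, and Benjamini-Hochberg adjusted p-values were held to 0.05. At each time 7 contrasts were tested, and an F test over 6 coefficients asked whether any group differed. The design and gene lists were fixed before the data were examined, whereas the filter and the pseudocount were set afterwards.

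One departure from the plan concerns the comparison of the times. It had been allowed only for raw counts over the same regions. The 2 tables hold identical regions, all scaled to the same constant, so limma was fitted across the deposited values of both tables. edgeR and DESeq2 on the recovered whole reads were run beside it and carry their own library scaling. The mean of terminal minus hepatectomy over the 7 conditions was tested with all 70 libraries.

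For each contrast the named genes followed 1 rule. Among regions past the threshold with a mean above the median of tested regions, up to 10 per direction with the largest change were named. With fewer than 5 regions past the threshold, the 3 regions per direction with the smallest unadjusted p were also named, as values that did not pass. Up to 4 members of each gene list with the smallest p could be named too. The 12 genes fixed in advance were Cyp2b1, Cyp2b2, Gstp1, Ggt1, Cdkn2a, Rassf1, Socs1, Igf2, H19, Dlk1, Meg3 and Dnmt1. Regions past the threshold with a mean below the median fell outside the rule, as did the regions of the F test, and they were named after their values were seen.

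The 14 gene lists covered phenobarbital response, preneoplastic focus markers, tumour suppressors, proto-oncogenes, imprinted genes, hepatocyte, biliary or progenitor, stellate or fibroblast, macrophage, endothelial and lymphocyte markers, methylation machinery, cell cycle and developmental homeobox genes. The last list also takes in the Pax, Tbx and Gata families. They were tested with camera at a preset correlation of 0.01 on 1 value per gene, the mean over its regions, with adjustment over the lists within a contrast. An estimated correlation was the alternative. Members were also adjusted over the list alone. The level of each list was set against 10000 random lists of the same size.

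Alternatives planned in advance were quantile normalization, no filter, pseudocounts of 0.1 and 10, a block for the replicate number, a covariate for the 4 blocks of library numbers in the titles, a fit to the groups of the contrast alone, camera on the region with the highest mean, and leaving out each library. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood, TMM), DESeq2 1.42.0, the omission of 9 weakly enriched libraries, the title number within a condition as a block for the comparison of the times, and, for the gene lists, quantile normalization, both blocks and the omission of each library. The regions that edgeR called within a time were fitted again in edgeR without each library, a test chosen after the edgeR result was seen. Other groupings were drawn 100 times for each result.

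The method was tested on simulated reads drawn from the means, totals and dispersions of the real regions, in which 200 regions were given a change of known size, 50 at each fold. Each region was drawn independently, so variation that a library shares over many regions was not simulated. The shares below may therefore be better than in the real data. For phenobarbital against water at partial hepatectomy, over 15809 regions, limma recovered 4% of changes of 1.25-fold, 30% at 1.5-fold, 66% at 2-fold and 90% at 3-fold. For the same contrast at terminal euthanasia, over 16008 regions, it recovered 0% at 1.25-fold, 8% at 1.5-fold, 52% at 2-fold and 90% at 3-fold. For the comparison of the times, over 16385 regions, it recovered 46%, 82%, 98% and 100% at these folds. Only increases were put in, in the phenobarbital or the terminal libraries, and decreases were not tried. The libraries kept their real totals, so a shift between groups in the deposited scaling added to these changes. For phenobarbital at 1.25-fold the limma median log2 difference was 0.44 at partial hepatectomy and 0.27 at terminal euthanasia, against 0.33 and 0.31 in edgeR. Unchanged regions were also called, against a threshold of 5%. For phenobarbital at partial hepatectomy limma called 6 beside 95 recovered (5.94% of its calls), edgeR 9 beside 91 (9%) and DESeq2 15 beside 95 (13.6%). At terminal euthanasia limma called 1 beside 75 (1.32%), edgeR 6 beside 87 (6.45%) and DESeq2 10 beside 92 (9.80%), and between the times limma called 4 beside 163 (2.40%) and edgeR 8 beside 164 (4.65%). Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading, tables and plots. Some genes that the rule named are not reported here. Ggt1 and Meg3 were not analysed here in the region tables, and a search of the authors' peak list gave 0 peaks for each. No genome sequence was used here.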

Results

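DNA methylation was measured around transcript starts in the livers of rats given a liver initiator or its vehicle and then the promoter phenobarbital. The initiators were diethylnitrosamine (DEN, a DNA-alkylating carcinogen) at 3 or 30 mg/kg, thioacetamide at 45 mg/kg, methapyrilene at 100 mg/kg and acetaminophen at 1000 mg/kg. A promoted control received 0.5% methylcellulose as vehicle and then phenobarbital at 500 ppm in the drinking water, and a water control received the vehicle and then plain water. Liver was taken at partial hepatectomy, after 1 week of promotion, and at terminal euthanasia, after 6 weeks. Each condition had 5 libraries at each time, 70 in all, and group values are means of the deposited signal ± SD with n = 5 unless another n is given.

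The scaling total of a library lay between 42.1 M and 56.6 M, and the regions held 0.933 M to 1.80 M recovered reads, or 2.01% to 3.68% of that total. The median region had 41 to 69 reads. Regions without a read made up 0.611% to 5.39% of a library. In 9 libraries this share was under 1%, at 0.932% or less, against 1.60% or more in the 61 others; these 9 are called weakly enriched libraries here, a name for the even spread of their reads, since enrichment itself was not measured. At partial hepatectomy they were replicate 5 of the water control, replicates 3 and 4 of DEN 30 mg/kg and replicate 5 of acetaminophen. At terminal euthanasia they were replicate 5 of the promoted control and 1 replicate each of DEN 30 mg/kg (3), thioacetamide (4), methapyrilene (3) and acetaminophen (3). All but replicate 5 of acetaminophen at partial hepatectomy carried block 3 of the 4 blocks of library numbers in the titles. Some libraries of block 3 were not weakly enriched. DEN 3 mg/kg had no library in block 3, so that block was not spread evenly over the groups. Replicate 5 of every initiator group carried the last block of library numbers in the titles, in which the regions held a median of 3.33% of the scaling total against 2.70% in the other blocks, and neither control group had a library in that block. The 10 libraries of that block also carried exactly the scaling totals of 10 libraries of the first block, in the same order of library number. Totals that repeat to the read in this order argue against both blocks carrying their own. In the block whose totals are not its own, the deposited signal would be off by a constant factor in each library. Its share of the scaling total, such as the 3.33%, would be off likewise. Recovered reads do not depend on the total, and in the regions their median was 1.58 M in the last block against 1.34 M in the others. This points to the last block but does not settle it, since a larger true share there was not tested. If it is the last block, the deposited signal is off in 1 replicate of every initiator group and in no control. The main limma fits use the deposited signal. edgeR, DESeq2 and quantile normalization rescale every library by its own values.

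**Figure D1:**
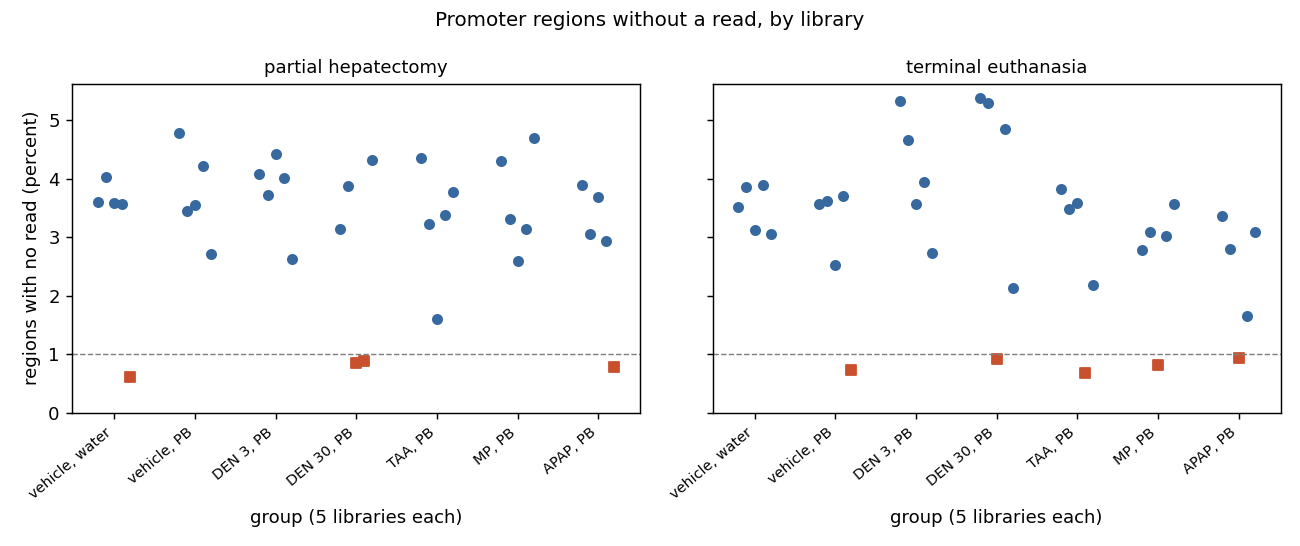
Share of regions without a read (percent, vertical axis) in each of the 70 libraries by group at both times; squares are the 9 weakly enriched libraries, circles the others, and the dashed line marks 1%. The squares lie at 0.932% or less and the circles at 1.60% or more.

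In the water control at partial hepatectomy, the median gene had a signal of 49.04, and 2 lists lay low against random lists of the same size. Developmental homeobox genes, regulators of body plan and organ identity, had a median of 18.2 over 87 genes, and genes of the phenobarbital response, among them cytochrome P450 and conjugating enzymes, had 17.5 over 39 genes. Imprinted genes lay high, at 91.4 over 32 genes and in the 99.6th percentile of random lists. Macrophage markers (111 over 15 genes), endothelial markers (124 over 7) and lymphocyte markers (92.2 over 17) lay in the 99.3rd, 97.3rd and 97.4th percentiles. H19, the imprinted non-coding RNA gene beside Igf2, had a mean of 430.4 ± 111. The signal counts enriched reads over a region and was not corrected for its sequence. Levels of different genes or lists are therefore not degrees of methylation.

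Of the genes fixed in advance, none passed in any treatment contrast at either time, and the smallest limma adjusted p among them was 0.53, for Gstp1. Gstp1, the placental glutathione transferase that marks preneoplastic foci in rat liver, had 28.5 ± 8.75 in the water control and 24.9 ± 6.40 in the promoted control at partial hepatectomy. Cyp2b1, the cytochrome P450 most strongly induced by phenobarbital, had 7.01 ± 3.56 and 5.62 ± 3.33 in the same groups. Socs1, an inhibitor of cytokine signalling, had 95.4 ± 37.7 and 135 ± 47.1, and Dnmt1, the maintenance methyltransferase, had 84.5 ± 12.5 and 82.7 ± 11.6. Over the 7 contrasts at partial hepatectomy the log2 differences ran from -0.56 to 1.10 for Gstp1, -0.53 to 0.29 for Cyp2b1, -0.28 to 0.55 for Socs1, -0.98 to 1.02 for the 3 regions of Igf2, -0.26 to 0.31 for H19, -0.45 to 0.38 for Dlk1, -0.18 to 0.35 for the 2 regions of Rassf1 and -0.10 to 0.04 for Dnmt1. At terminal euthanasia they ran from -0.18 to 0.23, -0.49 to 0.54, -0.35 to 0.37, -1.09 to 1.16, -0.26 to 0.30, -0.35 to 0.31, -0.23 to 0.36 and -0.42 to 0.43 in the same order. Cyp2b2 and Cdkn2a lay below the filter.

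Phenobarbital was compared with water to ask what promotion alone does to methylation. After 1 week the region of Nrg4, an epidermal growth factor family ligand, had 128 ± 8.29 in the promoted control and 79.6 ± 17.8 in the water control (log2 difference 0.71), and that of Stox2 had 33.4 ± 6.54 and 65.7 ± 15.2 (-0.95). Scarf1 and Mab21l2 each lay 0.69 higher, and Pptc7 and LOC361128 lay at -1.02 and -1.16. None passed, with limma adjusted p of 0.56 to 0.58. limma called 0 of 15809 regions, 993 had an unadjusted p under 0.05 (615 higher, 378 lower), and edgeR and DESeq2 called 0 each. Among listed genes, Abcb1b, a drug efflux pump of the phenobarbital response list, had 116 ± 16.3 and 74.3 ± 18.9, Alb, the albumin gene, 63.7 ± 9.93 and 37.9 ± 14.2, and Wt1, a zinc finger gene of the tumour suppressor list, 16.2 ± 17.3 and 34.6 ± 15.6. Adjusted over the list alone, each of these 3 passed in its own list, against 0 over all genes. Without replicate 2 of the promoted control, Wt1 passed over all regions (log2 difference -1.86, limma adjusted p = 0.045).

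Imprinted genes as a list lay higher under phenobarbital at partial hepatectomy, with 26 of 32 members higher, a median log2 difference of 0.21 against 0.06 for all genes, and a limma camera adjusted p of 0.022. It was not called with an estimated correlation (adjusted p = 0.84), and after quantile normalization the adjusted p was 0.25; over 6 alternatives it ran from 0.020 to 0.84. Calcr, the calcitonin receptor gene, had 149 ± 16.7 against 104 ± 19.3, and Cdkn1c, a cyclin-dependent kinase inhibitor, 121 ± 8.79 against 87.9 ± 22.4. None of the 32 passed, over all genes or adjusted over the list alone. Endothelial and lymphocyte markers lay higher in the same contrast without being called (limma camera adjusted p = 0.13 each). Without replicate 2 of the water control the list had an adjusted p of 0.067, and without replicate 2 of the promoted control 0.095. Replicate 5 of the water control was a weakly enriched library; without all such libraries the adjusted p was 0.020.

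After 6 weeks the region of Afg3l1 had 17.4 ± 5.60 under phenobarbital and 3.07 ± 3.01 under water (log2 difference 2.59, limma adjusted p = 0.18), and that of Hoxa10, a homeobox gene, 27.2 ± 28.9 and 2.86 ± 3.33 (2.90, limma adjusted p = 0.42). RGD1359380 lay 1.39 higher, and Samd12, P2ry2 and Pgcp lay at -0.94, -0.72 and -1.02. limma called 0 of 16008 regions, 507 had an unadjusted p under 0.05 (341 higher, 166 lower), and edgeR and DESeq2 called 0 each. Without replicate 4 of the water control, Afg3l1 passed (2.95, limma adjusted p = 0.036).

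Developmental homeobox genes lay higher under phenobarbital after 6 weeks, in 62 of 85 members, with a median log2 difference of 0.27 and a limma camera adjusted p of 1.1e-05. With an estimated correlation the call was lost (adjusted p = 0.90, the highest of 6 alternatives that began at 9.6e-06). Hoxd12 had 26.7 ± 18.5 against 5.88 ± 4.14, Hoxc12 23.9 ± 12.8 against 9.61 ± 8.95 and Lhx1 20.8 ± 17.3 against 5.35 ± 2.48. Adjusted over the list alone 2 members passed, both higher, against 0 over all genes. Replicate 5 of the promoted control was weakly enriched, and without it the adjusted p of the list was 0.18.

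DEN at 3 mg/kg was compared with vehicle, both promoted, to ask what a low dose of the initiator leaves behind. At partial hepatectomy the region of Rpp25 had 54.2 ± 19.7 after DEN and 106 ± 24.1 after vehicle (log2 difference -1.02), that of Ppp1r3c, a glycogen-targeting subunit of a protein phosphatase, 61.04 ± 8.20 and 99.7 ± 16.9 (-0.69), and that of Abcg3 43.3 ± 6.07 and 23.1 ± 6.10 (0.91). Defa6, LOC500118 and Dhx35 lay at 0.92, 1.29 and -0.87. None passed, with limma adjusted p of 1.00. Rgs5, a pericyte marker of the stellate list, had 57.1 ± 20.8 and 84.7 ± 14.5 and was the only member past the threshold when adjusted over the list alone, against 0 over all genes. limma called 0 of 15809 regions, 501 had an unadjusted p under 0.05 (331 higher, 170 lower), and edgeR and DESeq2 called 0 each.

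At terminal euthanasia Pygm, the muscle glycogen phosphorylase gene, had 129.99 ± 18.7 after DEN at 3 mg/kg and 74.6 ± 9.93 after vehicle (log2 difference 0.79), and Dpp3, a dipeptidyl peptidase gene, 64.1 ± 8.02 and 27.4 ± 10.5 (1.30). Ctsm lay at 1.12, Ifi44, an interferon-induced gene, at -1.59, Ube2cbp at -1.79 and LOC680885 at -1.36, all with a limma adjusted p of 0.58. Homeobox genes lay lower as a list, with 55 of 85 members lower, a median of -0.18 and a limma camera adjusted p of 0.00047. With an estimated correlation this call was lost (adjusted p = 0.86, the highest of 6 alternatives that began at 0.00041). Hoxd13 had 5.38 ± 3.91 against 22.7 ± 20.9 and Pax9 5.96 ± 6.77 against 19.9 ± 16.7, and 0 members passed, also when adjusted over the list alone. Without replicate 5 of the promoted control, a weakly enriched library, the adjusted p of the list was 0.32. limma called 0 of 16008 regions, 1363 had an unadjusted p under 0.05 (895 higher, 468 lower), and edgeR and DESeq2 called 0 each. Without replicate 5 of DEN 3 mg/kg, Ifi44 passed (-2.08, limma adjusted p = 0.010).

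DEN at 30 mg/kg gave the lowest adjusted p of the treatment contrasts. At partial hepatectomy the region of Mff, a mitochondrial fission factor gene on chromosome 9 from 82040736 to 82046361, had 63.4 ± 11.8 after DEN and 25.6 ± 7.89 after vehicle (log2 difference 1.30, limma adjusted p = 0.071). That of Tbx3, a T-box transcription factor gene on chromosome 12 from 38165545 to 38171170, had 98.5 ± 33.1 and 184 ± 24.8 (-0.96, limma adjusted p = 0.073). R3hdm2 (53.8 ± 19.2 and 20.9 ± 8.36), Commd3 (53.4 ± 9.42 and 25.5 ± 14.8) and Wfdc2 (58.6 ± 11.8 and 96.1 ± 13.3) also parted. RT1-CE5, a class I major histocompatibility gene, had 2.59 ± 2.24 against 45.0 ± 30.7 (-3.24, limma adjusted p = 0.27).

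limma called 0 of 15809 regions in this contrast, and 1208 had an unadjusted p under 0.05 (913 higher, 295 lower). edgeR called 1 region, Tbx3 (lower), and DESeq2 4, with Mff and R3hdm2 higher and Tbx3 and Cacng5 lower. In simulated data for phenobarbital against water at this time, unchanged regions made up 5.94% of the calls of limma, 9% of those of edgeR and 13.6% of those of DESeq2. These shares come from regions drawn independently with 200 changes put in, so they do not give the error of the few calls here. With a pseudocount of 10 limma called 5, namely Mff and R3hdm2 higher and Tbx3 and both transcripts of RT1-CE5, at 1 place, lower. Mff also passed in limma with the replicate number as a block (0.037), with the library number blocks (0.041) and in a fit to the groups of the contrast alone (0.021), and RT1-CE5 with the library number blocks (0.041). Over all alternatives and tools the adjusted p ran from 0.013 to 0.58 for Mff, highest without the weakly enriched libraries, from 0.0045 to 0.25 for Tbx3 and from 0.041 to 0.41 for RT1-CE5. The edgeR call of Tbx3 ended in 8 of 35 fits that left out 1 library, without replicate 1, 2, 3 or 5 of the promoted control or of DEN 30 mg/kg. Single libraries also changed limma's calls. Without replicate 4 of DEN 30 mg/kg, a weakly enriched library, Tbx3 passed. Without replicate 4 of the promoted control LOC500118, Mff, Pptc7 and Tbx3 passed, without its replicate 5 Commd3 and Mff, without its replicate 3 the place of RT1-CE5 (as 2 regions) and without its replicate 2 Wt1. Among listed genes, Txnrd1, a thioredoxin reductase gene of the focus marker list, had 139.6 ± 30.98 against 85.7 ± 6.51, Wt1 35.1 ± 16.6 against 16.2 ± 17.3 and Myc 20.7 ± 11.3 against 6.97 ± 1.42. Adjusted over the list alone, Txnrd1, Wt1 and Tbx3 each passed in their list, against 0 over all genes.

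At terminal euthanasia the region of Prodh2, a hydroxyproline dehydrogenase gene, had 83.6 ± 6.11 after DEN at 30 mg/kg and 47.2 ± 9.13 after vehicle (log2 difference 0.83, limma adjusted p = 0.60), and Rem1 and Rnase1l2 lay at 0.75 and 1.02. RT1-CE5 had 4.14 ± 6.93 against 29.9 ± 17.99 (-3.04, limma adjusted p = 0.25), and Trak2 lay at -2.21. Epdr1 lay at -1.37, and so did Sfrp4, a secreted Wnt antagonist gene whose region overlaps it; Sfrp4 was the only tumour suppressor past the threshold when adjusted over the list alone, against 0 over all genes. limma called 0 of 16008 regions, 546 had an unadjusted p under 0.05 (373 higher, 173 lower), and edgeR and DESeq2 called 0 each. RT1-CE5 passed without replicate 1 of DEN 30 mg/kg (-3.70, limma adjusted p = 0.0089) and without replicate 3 of the promoted control (-3.67, limma adjusted p = 0.0097), and with the library number blocks as a covariate.

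**Figure D2:**
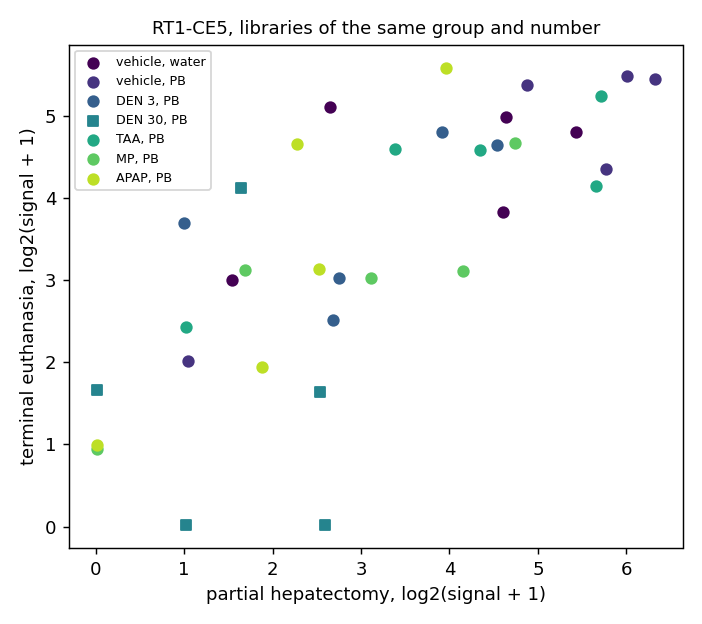
Signal of RT1-CE5 as log2(signal + 1) at partial hepatectomy (horizontal axis) and terminal euthanasia (vertical axis) for libraries of the same group and title number; squares are DEN 30 mg/kg, circles the other groups. In 8 of 35 numbers the signal lay below 5 at both times.

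The doses of DEN were compared with each other, although the higher dose was given for 1 week only. At partial hepatectomy Gstp1 had 37.4 ± 13.2 at 30 mg/kg and 16.3 ± 2.97 at 3 mg/kg (log2 difference 1.10, limma adjusted p = 0.53), and it passed when adjusted over the focus marker list alone, against 0 over all genes. Cox16, a cytochrome oxidase assembly gene, had 34.8 ± 11.6 and 8.48 ± 7.43 (2.23, limma adjusted p = 0.36), and B3galt4 55.3 ± 11.6 and 24.7 ± 9.31. Dnm1, a dynamin gene, lay at -0.61, and Pgcp, Grm7 (second copy) and Atp6v1c1 lay at 1.35, -1.21 and -0.80. limma called 0 of 15809 regions, 825 had an unadjusted p under 0.05 (592 higher, 233 lower), and edgeR and DESeq2 called 0 each. Without replicate 5 of DEN 30 mg/kg, Grm7 (second copy) passed (-1.48, limma adjusted p = 0.026).

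Homeobox genes lay higher at the higher dose at partial hepatectomy, in 58 of 84 members, with a median of 0.30 and a limma camera adjusted p of 0.0078. With an estimated correlation the call was lost (adjusted p = 0.90, the highest of 6 alternatives that began at 0.0069). Hoxb7 had 24.5 ± 14.2 against 6.87 ± 8.24, Hoxb8 29.6 ± 12.2 against 10.2 ± 6.01 and Hoxc4 35.7 ± 9.62 against 15.7 ± 10.9, while Tbx3 lay the other way at -0.68. Adjusted over the list alone 5 members passed, 4 of them higher, against 0 over all genes. Of the 5 libraries at the higher dose 2 were weakly enriched, and the adjusted p of the list was 0.24 without replicate 3 and 0.36 without replicate 4, the 2 in question, and 0.13 without replicate 4 of DEN 3 mg/kg. After quantile normalization it was 0.12, and with the library number blocks as a covariate 0.68.

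At terminal euthanasia the dose comparison gave Tpt1 37.2 ± 11.7 and 76.2 ± 20.9 (log2 difference -1.03, limma adjusted p = 0.78), and Cycs, the cytochrome c gene, 59.7 ± 13.6 and 104 ± 40.4 (-0.72). Andpro, Alg1 and RT1-CE5 lay at 1.98, 1.20 and -2.25. limma called 0 of 16008 regions, 482 had an unadjusted p under 0.05 (281 higher, 201 lower), edgeR called 1 (Bop1, higher) and DESeq2 0. Bop1 was highest in replicate 1 of DEN 30 mg/kg, with a signal of 763 in a group of 185 ± 323 and 40.6 ± 6.88 without it (n = 4), against 30.6 ± 10.3 at 3 mg/kg. Without that library the edgeR adjusted p rose from 0.013 to 0.84, the highest over the 35 fits that left out 1 library, of which the lowest was 0.00050. The call ended in 5 of these 35 fits, the others being those without replicate 1 (0.073), 2 (0.078), 3 (0.12) or 4 (0.10) of DEN 3 mg/kg. Homeobox genes lay higher in 54 of 85 members, with a median of 0.19 and a limma camera adjusted p of 0.00047. With an estimated correlation the call was lost (adjusted p = 0.93, the highest of 6 alternatives that began at 0.00043), and without replicate 3 of DEN 30 mg/kg, a weakly enriched library, the adjusted p was 0.13. With the library number blocks as a covariate it was 0.60, and 0 members passed when adjusted over the list alone.

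Thioacetamide, a hepatotoxicant that causes centrilobular injury, was set against vehicle. At partial hepatectomy the region of Klhdc9, on chromosome 13 from 87265020 to 87270645, had 142 ± 27.7 and 73.1 ± 22.8 (log2 difference 0.98, limma adjusted p = 0.40), and at terminal euthanasia it had 149 ± 44.4 and 84.9 ± 19.4 (0.79, limma adjusted p = 1.00). Wt1 had 39.7 ± 12.4 and 16.2 ± 17.3 at partial hepatectomy (1.64, limma adjusted p = 0.40), and Pdgfrb, the platelet-derived growth factor receptor of stellate cells, 120 ± 17.9 and 74.6 ± 15.8 (0.69). Wt1 and Pdgfrb each passed when adjusted over the list alone, against 0 over all genes, and without replicate 2 of the promoted control Wt1 passed over all regions (2.12, limma adjusted p = 0.0029). The same 5 promoted control libraries serve all contrasts with vehicle or water at this time. The repeated differences of Wt1 and Pdgfrb over these contrasts are therefore not independent. Wt1 had 34.6 ± 15.6 in the water control, which had no initiator. Lrrc19, Atp5g1, Ubr2 and Cd55 lay at 1.22, -0.74, -0.78 and -0.59. At terminal euthanasia Ttbk2, Synpo, LOC680885, Atp9b and Pth1r lay at 1.10, 0.83, -1.44, -1.81 and -0.90. limma called 0 of 15809 and 0 of 16008 regions at the 2 times, 702 (644 higher, 58 lower) and 330 (213 higher, 117 lower) had an unadjusted p under 0.05, and edgeR and DESeq2 called 0 each.

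Methapyrilene, an antihistamine that causes liver tumours in rats, was set against vehicle. At partial hepatectomy the region of Pptc7, a mitochondrial phosphatase gene, had 57.1 ± 8.77 and 27.2 ± 12.5 (log2 difference 1.16, limma adjusted p = 0.27), Otx1, a homeobox gene, 102 ± 21.3 and 46.1 ± 11.4 (1.14, limma adjusted p = 0.70), and C4bpa, a complement inhibitor gene, 38.9 ± 10.5 and 73.6 ± 20.9 (-0.90). Otx1 and Pdgfrb (114 ± 16.7 and 74.6 ± 15.8) each passed when adjusted over the list alone, against 0 over all genes. Without replicate 4 of the promoted control, Pptc7 passed (1.37, limma adjusted p = 0.016), and in a fit to the groups of the contrast alone Otx1 passed. Gpr137b, RGD1308601, Olr799 and Hook2 lay at 1.56, 1.04, -1.30 and -0.89. At terminal euthanasia Lrrc59 had 46.8 ± 6.01 and 82.7 ± 20.1 (-0.78), and Olr12, Wdr37, Luc7l2 and Adra1a lay at 2.01, 0.83, -2.43 and -1.05. limma called 0 of 15809 and 0 of 16008 regions at the 2 times, 580 (433 higher, 147 lower) and 411 (350 higher, 61 lower) had an unadjusted p under 0.05, and edgeR and DESeq2 called 0 each.

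Acetaminophen, an analgesic that is toxic to the liver at high doses, was the last initiator. At partial hepatectomy Nptx1 had 51.7 ± 18.6 and 85.7 ± 17.1 after vehicle (log2 difference -0.77), and Ifna1, an interferon alpha gene, 8.94 ± 11.7 and 41.1 ± 24.8 (-2.44). Sspo, Exoc3, Nrbf2 and Armcx1 lay at 1.77, 1.87, 1.26 and -1.43, all with a limma adjusted p of 0.99. At terminal euthanasia Cope, a coatomer subunit gene, had 68.5 ± 16.6 and 102 ± 17.4 (-0.59), and Ebna1bp2 had 36.5 ± 14.8 and 14.4 ± 3.43, while Lrig2, Nme7, Spint1 and Vom1r32 lay at 1.35, 0.96, -1.04 and -1.05. limma called 0 of 15809 and 0 of 16008 regions at the 2 times, 582 (301 higher, 281 lower) and 442 (381 higher, 61 lower) had an unadjusted p under 0.05, and edgeR and DESeq2 called 0 each. The median of all tested regions at terminal euthanasia was 0.11 with the deposited scaling and 0.01 over genes after quantile normalization.

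Relative to that shift, homeobox genes lay lower after acetaminophen at terminal euthanasia, with 44 of 85 members lower, a median of -0.03 and a limma camera adjusted p of 0.024. With an estimated correlation the call was lost (adjusted p = 0.97, the highest of 6 alternatives that began at 0.0029). It was also lost after quantile normalization (adjusted p = 0.13), and without replicate 1 of the promoted control (0.14) or replicates 1 (0.59), 2 (0.066) or 5 (0.51) of acetaminophen. Without replicate 5 of the promoted control, a weakly enriched library, the direction turned to higher (adjusted p = 0.86), and 0 members passed when adjusted over the list alone.

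Taking all 7 groups together, 1 region passed the F test at partial hepatectomy, named after its values were seen. This was Slc7a11, the cystine and glutamate exchanger gene, on chromosome 2 from 139315976 to 139321601 (limma adjusted p = 0.048). Its signal was 151 ± 41.7 after thioacetamide, 136 ± 34.2 and 113 ± 10.5 after DEN at 30 and 3 mg/kg, 86.1 ± 5.80 after methapyrilene, 72.4 ± 7.35 after acetaminophen, 105 ± 26.1 in the promoted control and 95.5 ± 21.2 in the water control. At terminal euthanasia the same region lay between 110.2 ± 18.5 after methapyrilene and 154 ± 25.1 after DEN at 3 mg/kg. In all, 658 regions had an unadjusted p under 0.05 at partial hepatectomy. edgeR called 3, namely Slc7a11, Tbx3 and RGD1309821, and DESeq2 Slc7a11, Tbx3 and Klhdc9. RGD1309821 was called because of replicate 4 of methapyrilene alone, with 423 in a group of 133 ± 163 and 60.5 ± 13.3 without it (n = 4), and without it the edgeR adjusted p was 0.90. The edgeR call of Tbx3 ended without replicate 1 (0.068) or 3 (0.058) of DEN 30 mg/kg, and that of Slc7a11, left in 34 of 35 omissions, without replicate 5 of thioacetamide (0.067).

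In limma the call of Slc7a11 lay close to the threshold. It ended in 21 of the 35 fits that left out 1 library, with limma adjusted p of 0.019 to 0.14 over the 35. These were the fits without any of the 5 libraries of DEN 3 mg/kg, without replicate 2 of the water control, 1 or 3 of the promoted control, 1 or 5 of DEN 30 mg/kg, 1, 3, 4 or 5 of thioacetamide, 2, 4 or 5 of methapyrilene, or 1, 2, 4 or 5 of acetaminophen. With the library number blocks as a covariate its limma adjusted p was 0.27, the highest over the tools and settings, of which DESeq2 gave the lowest, 0.00016. The last block held no control library.

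At terminal euthanasia the F test called 0 of 16008 regions in limma, with 409 at an unadjusted p under 0.05. edgeR called 3, namely Bop1, Hsf1 (which overlaps it) and Klhdc9, and DESeq2 called Klhdc9. Bop1 and Hsf1 were called because of replicate 1 of DEN 30 mg/kg alone; Hsf1 had 790 in that library, 211 ± 324 in its group and 66.3 ± 3.70 without it (n = 4). Without that library the edgeR adjusted p of both was 1.00, and every other omission left both called. The edgeR call of Klhdc9 ended without replicate 2 (0.066) or 5 (0.12) of thioacetamide, over 35 omissions that began at 0.00074. Whether a treatment difference itself changed between the times was tested as well, and limma called 0 of 16385 regions in each of 7 tests. The smallest adjusted p was 0.081, for the effect of phenobarbital on Samd12, and 297 to 1098 regions per test had an unadjusted p under 0.05; edgeR and DESeq2 were not run for these tests.

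Between the times, 11 regions rose toward terminal euthanasia and 0 fell, out of 16385 tested with 35 libraries at each time. Fam110a had 108 ± 21.1 against 73.2 ± 17.5 (n = 35 each, log2 difference 0.57, limma adjusted p = 3.8e-07). Septin9, a cytoskeletal GTPase gene, had 105 ± 29.9 against 67.7 ± 23.4 (0.65, limma adjusted p = 5.0e-06). Nr4a3, an orphan nuclear receptor gene, rose by 0.40, Sox7, an endothelial transcription factor gene, by 0.42, Gp1bb, a platelet glycoprotein gene, by 0.41, Arhgef2 by 0.45, Znf597 by 0.37 and the histone gene Hist1h2bn by 0.46. The 3 others, named after their values were seen since their means lay below the median, were the histone gene Hist1h4b (24.99 ± 10.3 against 14.6 ± 9.68), Cdk5r1 (53.5 ± 17.8 against 36.8 ± 13.3) and the Polycomb gene Cbx8 (28.6 ± 14.8 against 15.9 ± 12.9). In all 7 conditions 10 of the regions were higher at terminal euthanasia, and Znf597 in 6.

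**Figure D3:**
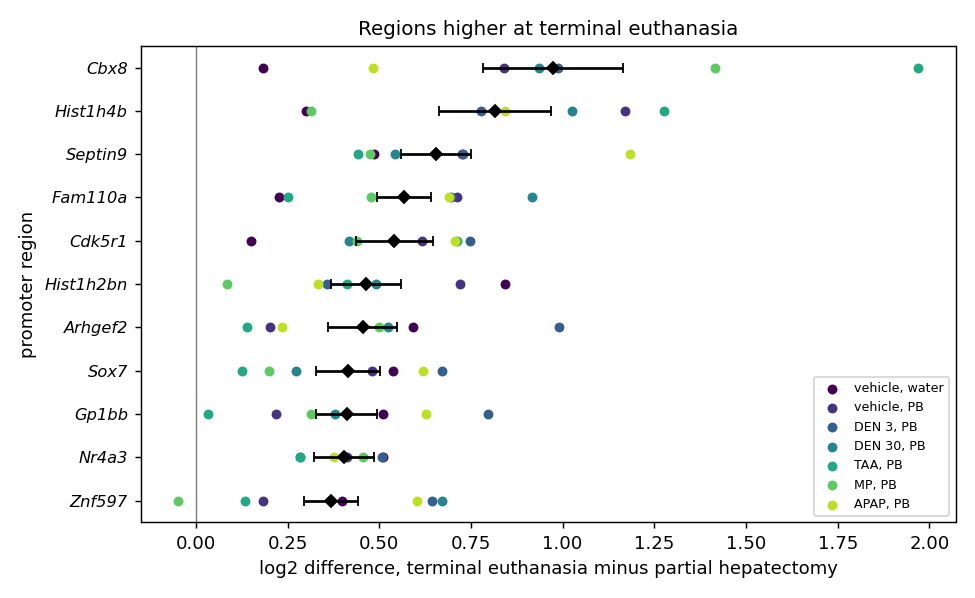
Log2 difference between terminal euthanasia and partial hepatectomy (horizontal axis) for the 11 regions past the threshold; coloured dots are the 7 conditions and black diamonds the mean over conditions with its standard error. The means run from 0.37 for Znf597 to 0.97 for Cbx8.

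This comparison departs from the plan, which allowed it for raw counts alone. On recovered reads edgeR called 11 regions higher and 6 lower and DESeq2 11 higher and 7 lower, and quantile normalization gave 15 higher and 10 lower; each called the same 11 regions higher. At an unadjusted p under 0.05, 985 regions were higher and 94 lower. Among the lower regions outside the rule, DESeq2 gave Tmem176a (-0.47), Ddt (-0.34), P2ry2 (-0.34), Cym (-0.31), Osmr (-0.26), Ddo (-0.26) and Socs3 (-0.24), chosen after their values were seen, and limma with the deposited scaling called none of them.

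Listed genes between the times included Ccnb2, a mitotic cyclin gene, with 45.2 ± 15.7 against 33.7 ± 14.4 (n = 35 each), Slc7a11 with 127 ± 25.1 against 108 ± 34.2 and Srxn1, the sulfiredoxin gene, with 84.3 ± 19.04 against 70.5 ± 14.7; none passed over all regions. Adjusted over the list alone, 3 focus markers, 1 cell cycle gene and 5 homeobox genes passed, all higher, against 0 over all genes. Homeobox genes lay higher at terminal euthanasia in 76 of 85 members, with a median of 0.16 against 0.05 for all genes and a limma camera adjusted p of 0.00013. With an estimated correlation the call was lost (adjusted p = 0.95, the highest of 6 alternatives that began at 1.1e-05). Hoxa9 had 90.1 ± 21.9 against 72.5 ± 18.7 and Nkx6-2 26.6 ± 12.4 against 19.01 ± 13.7. Nkx6-2 passed over all regions with the title number as a block (limma adjusted p = 0.028), the lowest of 10 alternatives that reached 0.74. There were 4 weakly enriched libraries at partial hepatectomy and 5 at terminal euthanasia, and without them the adjusted p of the list was 0.045.

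**Figure D4:**
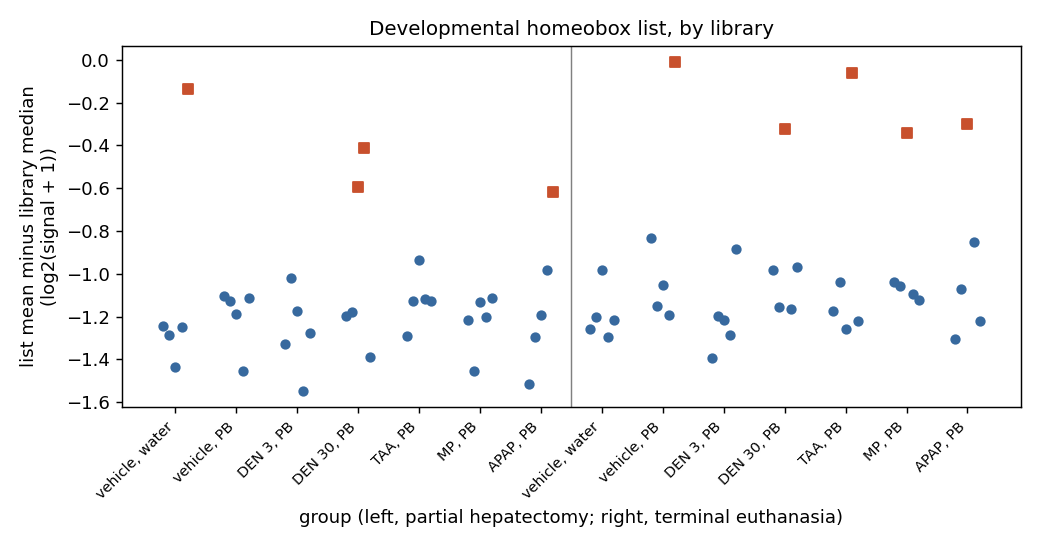
Mean of the developmental homeobox list minus the median of the library, both as log2(signal + 1) (vertical axis), in each of the 70 libraries by group; squares are the 9 weakly enriched libraries. All squares lie above all circles, and above the mean of the other libraries of their group by 0.63 to 1.17.

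Across all 15 contrasts camera called 7 of 210 tests of a list, 6 for the homeobox genes and 1 for the imprinted genes, and none held with an estimated correlation. The other 12 lists were not called in any contrast. Their smallest camera adjusted p was 0.13 for endothelial and for lymphocyte markers and 0.39 for methylation machinery, each higher for phenobarbital against water at partial hepatectomy. Phenobarbital response genes (0.20) and stellate markers (0.44) reached theirs between the times, both lower. Tumour suppressors (0.33) and cell cycle genes (0.24) reached theirs for DEN 30 mg/kg against vehicle at terminal euthanasia, both lower. Hepatocyte markers (0.18), biliary markers (0.24) and proto-oncogenes (0.36) did so for the doses of DEN at terminal euthanasia, macrophage markers (0.30, lower) for the doses at partial hepatectomy, and focus markers (0.34) for DEN 3 mg/kg at terminal euthanasia.

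The direction of the regions with an unadjusted p under 0.05 depended on the scaling. With the deposited scaling the median log2 difference over all regions ran from -0.03 to 0.11 over the treatment contrasts and was 0.05 between the times, and after quantile normalization it lay between -0.01 and 0.01. At partial hepatectomy the limma counts after quantile normalization were 540 higher and 424 lower for phenobarbital, 272 and 258 for DEN 3 mg/kg, 537 and 615 for DEN 30 mg/kg, 281 and 240 for thioacetamide, 293 and 267 for methapyrilene, 342 and 377 for acetaminophen, and 453 and 510 for the doses. At terminal euthanasia they were 447 and 511, 559 and 512, 495 and 414, 453 and 417, 443 and 397, 403 and 374, and 273 and 272 in the same order, and between the times 604 and 503.

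The share of regions whose groups did not overlap at all was 0.27% to 1.20% over the treatment contrasts. Chance gives 0.794% for 5 libraries against 5. A difference of 2 standard errors corresponded to 1.31-fold at partial hepatectomy and 1.34-fold at terminal euthanasia in regions with a signal above the median, and to 1.11-fold between the times.

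The authors' deposited table at partial hepatectomy lists an unadjusted p under 0.05 against the promoted control for 651 regions in the water control, 564 after DEN at 3 mg/kg, 895 after DEN at 30 mg/kg, 734 after thioacetamide, 670 after methapyrilene and 504 after acetaminophen. The authors' deposited table at terminal euthanasia lists 360, 737, 407, 396, 698 and 506 in the same order. These counts are 2.95% to 5.23% of the regions with a p-value at partial hepatectomy and 2.11% to 4.31% at terminal euthanasia. Chance alone gives about 5% at this threshold.

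The authors' peak list sets DEN 30 mg/kg against phenobarbital over the whole genome and holds 35323 peaks, of median width 180 to 184 bp. At the first time 27721 were higher after DEN and 1334 lower, and at the second 2016 were higher and 4252 lower. Most lay away from genes, with 57.3% of the higher and 61.8% of the lower peaks intergenic at the first time and 56.3% and 60.4% at the second; introns held 34.4%, 28.6%, 32.3% and 31.5% of them, and 1191 peaks (3.37%) touched a region of the tables. Of the 4252 lower peaks at the second time, 94 (2.21%) overlapped a lower peak of the first, and of the 2016 higher peaks 113 (5.61%) overlapped a higher one. Between directions, 66 lower peaks of the second time (1.55%) and 2 higher ones (0.0992%) overlapped peaks of the opposite direction.

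An intron of Tmem132c on chromosome 12 held the largest peak, from 30182377 to 30182548, with the authors' counts of 7250 reads against 24 at the first time, and from 30182365 to 30182545 with 2246 against 23 at the second. Lower peaks seen at both times included an intergenic one on chromosome 13 from 94176310 to 94177813, with 328 reads against 0 at the first time and 322 against 1 at the second, and one on chromosome 10 from 97624903, with 593 against 58 and 527 against 49. Tbx3 carried a lower peak inside its region at the first time, from 38169671 to 38169996 with 52 reads against 7, and a higher one just outside it at the second, from 38171466 to 38171635 with 20 against 3. Mff carried 2 higher intron peaks at the first time, from 82047017 to 82047199 with 23 reads against 2 and from 82055464 to 82055696 with 22 against 1. Both lay outside the region of Mff given above, so they do not measure the same place. Socs1 carried a higher peak upstream at the first time with 17 against 1. The peaks carry no replicate error, and no test between groups was made on them.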

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

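The tests of scaling and of longer phenobarbital exposure for the regions that rose between the times were chosen only after the result was seen, the condition that the latter hold without each region was added after its value was seen, as was the omission of libraries from it, and edgeR, DESeq2 and the omission of weakly enriched libraries were added after the data were examined.

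A single library lay far from the 4 others of its group in 14 of 182 groups of values tested, and chance gives about 1 in 20. The share of regions without a read was 0.611% in replicate 5 of the water control at partial hepatectomy (nearest library 3.58%) and 0.815% in replicate 3 of methapyrilene at terminal euthanasia (2.78%). Replicate 5 of the water control at partial hepatectomy also stood apart in Cbx8 (32.4, nearest 11.6), Hist1h4b (57.7, nearest 19.5) and, on the low side, Znf597 (74.9, nearest 111). The weakly enriched replicate 5 of the promoted control at terminal euthanasia had 58.4 in Cbx8 (29.7), and that of acetaminophen at partial hepatectomy 22.3 in Hist1h4b (14.3). The remaining libraries were not weakly enriched. Those of DEN 3 mg/kg at partial hepatectomy had 38.99 in Arhgef2 (replicate 5, nearest 70.8, on the low side) and 33.9 in Hist1h4b (replicate 4, nearest 9.77). At terminal euthanasia replicate 2 of DEN 3 mg/kg had 209.3 in Sox7 (100.2) and 98.8 in Cdk5r1 (64.4), and replicate 5 of thioacetamide 209.2 in Sox7 (111). Replicate 5 of thioacetamide at partial hepatectomy had 494 in Gp1bb (273), and replicate 4 of the water control 83.1 in Hist1h2bn (43.5).

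The developmental homeobox list was called in 5 treatment contrasts and between the times, and 0 of these 6 calls was left with an estimated correlation. Its mean relative to the library lay higher in 9 of 9 weakly enriched libraries, by 0.63 to 1.17, against an SD of 0.17 in the others. This is partly built in, since these libraries were chosen for few regions without a read and the list is low in signal. Its median was 18.2 against 49.04 for all genes in the water control at partial hepatectomy. The higher mean alone therefore does not point to low enrichment. Without the weakly enriched libraries 1 of the 6 calls was left, the one between the times, so low enrichment may explain the 5 calls between treatments. The deposited scaling as the whole source is argued against, since 4 of the calls were left after quantile normalization. Enrichment itself was not measured, and initiation and promotion were not tested as sources. Except for replicate 5 of acetaminophen at partial hepatectomy, the weakly enriched libraries carried block 3 of the library numbers, which was not separated from low enrichment.

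Higher peaks outnumbered lower ones 20.8 to 1 at the first time in the authors' list of DEN 30 mg/kg against phenobarbital. In the 885 regions with such a higher peak the DEN 30 mg/kg libraries exceeded vehicle by 0.083 (log2, relative to regions with no peak of the first time). Of that excess 77.2% was left without the weakly enriched libraries of the group, between the bounds set for and against them as the source. The other 3 libraries of the group all lay above the vehicle mean by more than its SD of 0.021, as did 19 of 25 libraries of the other groups, but these values decide nothing, since the regions were chosen for peaks called between these groups, which builds low vehicle values in. At terminal euthanasia the excess was -0.00039 with a vehicle SD of 0.026, so no carried excess was seen at a size above that spread. Low enrichment and initiation cannot be told apart for these peaks, since 2 of the 5 libraries were weakly enriched and the list gives no value per library.

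The 11 regions that rose between the times were all left under the scalings tried (11 in the lower of quantile normalization and edgeR) and without the weakly enriched libraries (11), which argues against both as the source. The water control rose as well, by a mean log2 of 0.43 (SE 0.10) against 0.57 (SE 0.05) in the phenobarbital groups. It rose less than they did in Fam110a (0.23 against 0.62), Hist1h4b (0.30, 0.90), Cdk5r1 (0.15, 0.61), Cbx8 (0.18, 1.11) and Septin9 (0.49, 0.68). It rose more in Hist1h2bn (0.84, 0.40), Nr4a3 (0.51, 0.39), Gp1bb (0.51, 0.39), Arhgef2 (0.59, 0.43), Sox7 (0.54, 0.40) and Znf597 (0.40, 0.36). None of these differences passed (limma adjusted p of 0.36 to 0.88). Single water libraries moved these rises both ways. Without the weakly enriched replicate 5 of the water control at partial hepatectomy Hist1h4b rose by 0.68 and Cbx8 by 0.54. Hist1h4b rose by 0.08 without replicate 1 at partial hepatectomy, and Cbx8 was -0.13 without replicate 4 at terminal euthanasia. Cdk5r1 ran from -0.11 without replicate 4 at partial hepatectomy to 0.32 without replicate 3 at terminal euthanasia. Over the set the rise in water (0.48 without the weakly enriched water library) passed the bound set against longer phenobarbital exposure as the whole source. It did so in 9 of the 11 fits that left out 1 region (11 of 11 without that library). It did not without Hist1h2bn (0.39, 0.59), Arhgef2 (0.41, 0.59) or replicate 1 (0.39) or 4 (0.37) of the water control at terminal euthanasia. These values decide nothing, since the regions were chosen for a high mean rise over 7 conditions that include the water control. A rise in water is thus partly built in, and longer phenobarbital exposure stays open. A rise in methylation is a hypothesis only, since differences that all groups share remain open and none was tested: age, regrowth after hepatectomy, the surgery and the processing of each time's libraries, which the design confounds with time.

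Other groupings of the same libraries were drawn 100 at a time, the real one included, and counted by regions at an unadjusted p under 0.05. At partial hepatectomy as many regions as in the real grouping came from 32 groupings for phenobarbital (real 993, highest other 2254), 62 for DEN 3 mg/kg (501, 861), 22 for DEN 30 mg/kg (1208, 2735), 21 for thioacetamide (702, 1171), 30 for methapyrilene (580, 1010), 65 for acetaminophen (582, 1739), 32 for the doses (825, 3092) and 38 for the F test (658, 3413). At terminal euthanasia these were 70 (507, 1358), 9 (1363, 2539), 61 (546, 3761), 95 (330, 4083), 56 (411, 2704), 72 (442, 3545), 84 (482, 2000) and 80 (409, 3043) in the same order. Chance was not excluded for any of these. Between the times 2 groupings of 100, the real one among them, called as many regions as the real 11, and the highest other called 937. This share lay under the 0.05 set beforehand, but it does not exclude chance. The draws took the libraries as independent, and a grouping that calls 937 points to a structure of the samples apart from time. For the gene lists between the times 28 groupings called as many (real 1, highest other 3), which does not exclude chance.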

How the results depend on the processing

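Chosen after the data were seen were edgeR, DESeq2, the omission of weakly enriched libraries, the title number as a block for the times and, for the gene lists, quantile normalization, both blocks and the omission of single libraries. The edgeR fits without each library were chosen only after the edgeR result was seen.

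For DEN 30 mg/kg against vehicle at partial hepatectomy limma called 0 regions with the main settings, 5 with a pseudocount of 10, 1 with the replicate number as a block, 3 with the library number blocks and 3 in a fit to the groups of the contrast alone; edgeR called 1 and DESeq2 4. The F test at this time, with 1 call, gave 2 after quantile normalization, 0 with no filter, 0 with a pseudocount of 0.1, 2 with a pseudocount of 10, 0 with the library number blocks, 3 in edgeR and 3 in DESeq2. Methapyrilene against vehicle gave 1 (Otx1) in a fit to its groups alone. At terminal euthanasia the F test, with 0 calls, gave 1 after quantile normalization, 3 in edgeR and 1 in DESeq2. DEN 30 mg/kg gave 2 with the library number blocks, DEN 3 mg/kg 1 (Fam111a) in a fit to its groups alone, and the doses 1 in edgeR. Without replicate 1 of DEN 30 mg/kg 2 of the 3 edgeR calls of this F test ended (Bop1 and Hsf1), as did that of the doses, which 4 other omissions also ended; without replicate 4 of methapyrilene 1 of the 3 at partial hepatectomy ended. Other causes were not tested.

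Between the times the 11 calls became 25 after quantile normalization, 22 without the weakly enriched libraries, 17 in edgeR and 18 in DESeq2, and 11 to 14 in the other settings; the same 11 regions were called higher in each, and the cause of the added calls was not tested. The 7 calls of gene lists became 0 with an estimated correlation, 4 after quantile normalization and 2 without the weakly enriched libraries. With an estimated correlation the camera adjusted p of these 7 calls ran from 0.84 to 0.97. Such an estimate widens the error of a list only where it exceeds the preset correlation, so the loss is not built in. The p-values under the preset correlation may therefore be too small. The estimates themselves are not reported here.

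Leaving out each library in turn gave, at partial hepatectomy, 0 to 1 regions for phenobarbital, 0 to 4 for DEN 30 mg/kg, 0 to 1 for thioacetamide, 0 to 1 for methapyrilene, 0 to 1 for the doses, 0 to 4 for the F test, and 0 throughout for DEN 3 mg/kg and acetaminophen. At terminal euthanasia it gave 0 to 1 for phenobarbital, 0 to 1 for DEN 3 mg/kg, 0 to 2 for DEN 30 mg/kg and 0 throughout for the others. Between the times it gave 11 to 14 regions, and for the gene lists 5 to 8 calls, the 5 without replicate 5 of the promoted control at terminal euthanasia.

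Of 3258 values of named genes under the alternatives, 3124 kept their direction and side of the threshold or moved by less than their spread, 118 moved further, 16 newly passed and 0 reversed; in 120 the sign changed without passing. Same-numbered libraries of different groups within a time, checked for the replicate block, had median correlations of 0.0083 and 0.022, with 25 and 24 of 105 pairs over 0.1. The medians of differently numbered pairs were 0.00071 and 0.0056. The best match in another group carried the own number in 10 and 9 of 35 libraries. No clear pairing across groups was seen, but no components were removed, so a weak pairing is not excluded. In simulated data for phenobarbital against water over 15809 regions at partial hepatectomy, drawn independently, limma recovered 30% of increases of 1.5-fold and 66% at 2-fold.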

Other observations

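The test of whether same-numbered libraries come from the same animal was chosen only after the result was seen.

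Libraries of the 2 times that share a title number within a group were compared by correlation across regions, after removal of the first 2 principal components. The best match within the group carried the own number in 31 of 35 libraries, where chance gives 7 and the highest of 10000 permutations gave 18 (permutation p = 1e-04, the smallest they can give). With 0 to 5 components removed the count was 21, 32, 31, 34, 35 and 34. A shared block of library numbers as the only source is argued against, since the own number correlated more than the block mate in 100% of 28 comparisons. The same number may therefore stand for the same animal at both times, a hypothesis that the labels do not state. Without removal of components the correlations of the pairs ran from -0.38 to 0.68 and exceeded 0.1 in 11 of 35. The main comparison of the times took the libraries as independent, as did the tests of whether a treatment difference changed between the times. If the numbers stand for animals, these fits leave the pairing out. With the title number as a block limma called 14 regions between the times, and the tests of changed treatment differences were not repeated with it.

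RT1-CE5 was listed for 2 transcripts at 1 place, on chromosome 20 from 3512607 to 3518232. Within groups, its values in same-numbered libraries of the 2 times correlated at r = 0.66 (one-sided permutation p = 1e-04), at 0.56 without the 2 farthest numbers, and by rank at 0.59 (one-sided permutation p = 0.00033). The signal lay below 5 at both times in 8 of 35 numbers, at 1 time in 8 and at neither in 19. A difference carried by each animal, such as a variant in an outbred strain, may therefore explain part of its low signal after DEN at 30 mg/kg, and no genotype was measured here.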
